A study of Homo sapiens with 8 samples.

How the data were processed

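Total RNA of 4 human prostate cancer cell lines was compared on spotted oligonucleotide arrays with 2 colours. Every array held cDNA of cells given both drugs and cDNA of mock cells of the same line, given PBS and ethanol, per the labels' protocols. The 8 arrays were grouped by line, and the dye of each channel was taken from the labels. Ratios were turned so that a value above 0 means more RNA in treated cells.

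The deposited scanner files hold an intensity per spot and channel, with foreground and local background mean, median and standard deviation, made with an image analysis program in version 5.5, per the file headers. Spots were outlined by automatic segmentation on 6 arrays and by fixed circles on the PC3 pair, and a spot was called empty under 4 background SD on 5 arrays and under 2 on 3 (LNCaP replicate 1 and the MDA2b pair), per the file headers. The deposited value table holds log2 ratios of the authors, whose normalization is not given in the sources used here. Set against the scanner values of the same arrays, its columns ran in the direction treated over mock and on a log2 scale (Pearson r from 0.762 to 0.967 over bright spots), with column medians from -0.0255 to 0.0206. The exact method of its centring stays unknown. Empty cells of the table, 489 to 1954 per array, all lay at spots not above background.

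Spot order was checked against the other arrays. MDA2b replicate 1 correlated with them at Spearman -0.09 (treated) and -0.15 (mock) as deposited and at 0.67 and 0.66 after turning the grid by 180 degrees, and its blank spots had a median signal over background of 314 and 460 as deposited against 11.7 and 9.07 turned. The turned order was used throughout, for the column of the value table as well; this was chosen after the data were seen.

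Of 15552 spots per array 735 were controls (576 blank and 159 Arabidopsis) and 14817 held human probes with 14802 different texts; spots of 1 probe were averaged. Names came from the probe text through a RefSeq gene table: 9973 probes had 1 current symbol (8792 by RefSeq accession, 577 by the symbol and 604 by an older symbol), 55 had several and 4789 none. Only probes with 1 symbol are named, and genes of chromosome Y and XIST are not named. No coordinates are given, since the files name no genome build.

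Background was corrected with normexp (offset 50), and log2 ratios were normalized by loess within each array with control spots at weight 0, in limma 3.58.1 under R 4.3.3 (statmod 1.5.0). A spot was above background when its mean exceeded the local background mean by 2 background SD. A probe was above background in a line when at least 1 channel was on both of its arrays, and it was tested when this held in at least 2 lines. Signals per array limit precision: median foreground signals ran from 46.1 to 837 and median local backgrounds from 23.4 to 441. Leaving out spots called empty in both channels was planned as the main setting before the data were examined. That call proved to be one of dimness with unequal thresholds between arrays, which filters the lines unequally. Those spots were therefore kept, with the uniform limit of 2 SD, and leaving them out became the alternative. This choice was made final after the number of probes with the spots kept had been seen, and it decides whether TIMP1 passes.

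For the change across lines, the 2 arrays of a line were averaged, which cancels the dye effect, and the 4 averages were tested against 0 with lmFit and eBayes and Benjamini-Hochberg adjustment (threshold 0.05). SDs are those between lines. Within a line there was no test, and probes changed at least 2-fold on both arrays were counted. Differences between lines were tested with a moderated F test on the 8 arrays with a dye term. The labels name no second culture of a line, so these p-values measure only a technical spread. Gene lists used 1 probe per gene, the brightest, with camera at a preset correlation of 0.01, camera with an estimated correlation and fry, over lists of at least 3 tested genes. Camera takes its degrees of freedom from the number of genes with a preset correlation, and from the 4 lines with an estimated one. The 21 lists were genes methylated in prostate cancer, cancer-testis genes, genes induced and repressed by deacetylase inhibitors, histones, proliferation, p53 response, interferon-stimulated, androgen response, metallothioneins, neuronal and neuroendocrine, imprinted, endoplasmic reticulum and amino acid stress, cholesterol and lipid synthesis, DNA methyltransferases and histone deacetylases, antigen presentation, cell adhesion and junctions, ribosomal proteins, and markers of fibroblasts, leukocytes and endothelium. A mock signal not above background on either array gives only a bound. This bound is approximate, as the level used in place of the mock signal was not the limit of the spot itself. For it, the mean treated level after loess and Aquantile normalization was set against the mean of, per array, the lowest mock level among probes above background or the probe's own level if higher; with the dyes balanced within a line the dye effect largely cancels.

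Named genes followed a rule. Across lines these were up to 12 higher and 10 lower probes past the threshold with 1 direction on all 8 arrays, with remaining places going to the smallest unadjusted p among probes with 1 direction on all 8 and a mean of at least 2-fold. Within a line the 5 largest increases and 3 largest decreases were named. Between lines these were the 6 smallest p among probes at least 2-fold up in one line and down in another, on both arrays of each. Among genes switched on, the 6 seen in the most lines were named (ties by mean log2 ratio), and in a list up to 4 members past an adjusted p of 0.05. GSTP1, CDKN1A, DNMT1, KLK3 and TYMS were always named. Other members of lists are given by the size of their mean change, which was looked up after the values were seen.

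The functions were tested on simulated data. For the change across lines, over 9087 probes with the real spread, 63% of 100 changes of 1 on the log2 scale and 96% of 100 changes of 2 were found, with 7 false among 166 calls. For the differences between lines, 0% and 54% were found, with 5 false among 59 calls. Alternatives were no background correction, an offset of 10, median centring, Aquantile between arrays, spot medians, the value table, other filters on dim probes, other models for the replicates, other thresholds, and leaving out each line or array. Those added after the data were seen were MDA2b replicate 1 as deposited, loess within blocks of the print grid, a uniform limit of 4 SD, terms for the image analysis set, overlap without LNCaP, and the gene lists without LNCaP replicate 1 or MDA2b replicate 1. Files were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.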

Results

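The study looked for genes that are silenced by DNA hypermethylation in prostate cancer and come back after treatment with 2 drugs. 5-aza-2'-deoxycytidine blocks DNA methyltransferases, and trichostatin A blocks histone deacetylases. Both were given to 4 prostate cancer cell lines: DU-145 and PC3, which are androgen-independent, and LNCaP and MDA2b, which carry an androgen receptor and make prostate-specific antigen. The labels give 5-aza-2'-deoxycytidine at 5 mM at 0, 24 and 72 h and trichostatin A at 500 nM for the last 24 h. RNA of treated cells was hybridised on a spotted 2-colour array against RNA of mock-treated cells of the same line. Each line had 2 arrays with opposite dyes, treated RNA in Cy5 on replicate 1 and in Cy3 on replicate 2, which makes 8 arrays. Each array carried 15552 spots with 14802 different human probes, of which 9973 had 1 current gene symbol. Signals above background were found for 43.2% to 79.3% of human spots in the Cy3 channel and for 17.9% to 45.2% in the Cy5 channel. Both arrays of a line measured the same kind of RNA pair and the labels name no further culture, so each line counted as 1 replicate and the precision is limited by n = 4 lines.

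The first comparison asked which genes changed with treatment in all 4 lines. TIMP1, a secreted inhibitor of matrix metalloproteinases, was higher on all 8 arrays, by 1.98 ± 0.37 on the log2 scale (SD, n = 4 lines), which is 3.96-fold (limma, adjusted p = 0.0262). Its log2 ratio was 2.47 in DU-145, 1.86 in LNCaP, 1.59 in MDA2b and 2.02 in PC3. In LNCaP the mock signal of TIMP1 was not above background on either array, and the treated signal there was at least about 2.49-fold higher. It was the only 1 of 9087 probes past the threshold, and no probe was past it in the lower direction. With the spots called empty by the image software left out, which was the setting planned before the data were examined, 4951 probes were tested and none passed (TIMP1 at 2.03, adjusted p = 0.329). At an unadjusted p under 0.05 there were 621 probes, 334 higher and 287 lower, against 454 expected by chance.

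A further 11 genes were named because they were higher on all 8 arrays with a mean of at least 2-fold, although none passed the adjusted threshold. Cholecystokinin, CCK, a peptide hormone, had a mean log2 ratio of 1.40 ± 0.36 (SD, n = 4 lines) and an adjusted p of 0.103. The linker histone gene H1-2 stood at 1.82 ± 0.94, the growth factor gene IGF2 at 1.34 ± 0.67 and the small heat shock protein gene CRYAB at 1.34 ± 0.70. IFI30, a lysosomal thiol reductase of antigen processing, stood at 1.20 ± 0.47, and NFKBIA, the inhibitor of NF-kappaB, at 1.18 ± 0.62. PLAT, tissue plasminogen activator, had 1.15 ± 0.49, and the stress response gene IER3 1.14 ± 0.60. CDKN1A, a cyclin-dependent kinase inhibitor, had 1.07 ± 0.48, ENC1 had 1.05 ± 0.51 and the germ cell alkaline phosphatase gene ALPG had 1.01 ± 0.58. Adjusted p-values of these 11 genes ran from 0.103 to 0.452. Some single arrays lay close to 0: CCK at 0.0014 and IGF2 at 0.015 on MDA2b replicate 1, and ALPG at 0.0004 on PC3 replicate 2. On the other MDA2b array CCK stood at 1.82. Mock signals were not above background for CCK and PLAT in DU-145 and LNCaP and for IGF2 and ALPG in LNCaP, so that their ratios there, and the means that include them, are uncertain. Among all probes, 108 were higher and 77 lower on all 8 arrays, against 71.0 expected in both directions together if directions were independent. Both arrays of a line measured the same comparison, so directions are not independent, and the excess over 71.0 does not show a shared response. Of the 108, 24 reached a mean of 2-fold, and of the 77 none did, so that no lower gene met the rule.

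**Figure D1:**
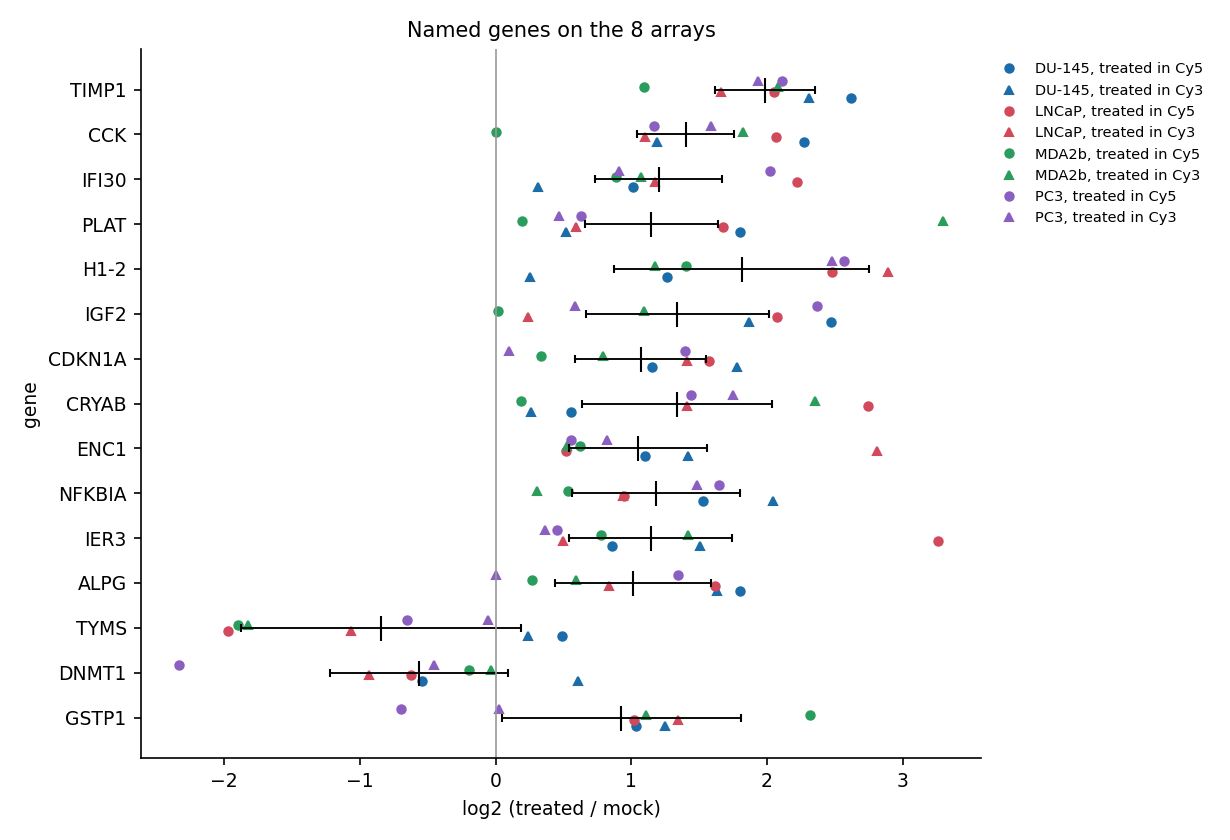
Log2 ratio of treated over mock (horizontal axis) for the 12 genes named by the rule and 3 other genes named in advance (vertical axis). Points are single arrays, coloured by line and shaped by the dye of the treated RNA, and the black bar is the mean of the 4 line averages with its SD; TIMP1 lies above 1 on all 8 arrays.

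GSTP1, a glutathione transferase gene whose promoter is methylated in most prostate cancers, had log2 ratios of 1.14 in DU-145 and -0.34 in PC3, where its mock signal was above background on both arrays. In PC3 its treated signal was above background on only 1 array, and the arrays gave -0.70 and 0.02, so that ratio is uncertain. In LNCaP and MDA2b its mock signal was above background on no array and its treated signal on 1 array each, so that neither a ratio nor a bound can be given there. The mean over the lines, 0.93 ± 0.88 (SD, n = 4 lines, limma adjusted p = 0.647), includes those uncertain ratios. Thymidylate synthase, TYMS, stood at -1.86 in MDA2b and -1.52 in LNCaP but at -0.35 in PC3 and 0.36 in DU-145 (mean -0.84 ± 1.03, adjusted p = 0.716). The maintenance DNA methyltransferase gene DNMT1 had a mean of -0.56 ± 0.66, with -1.39 in PC3 (limma adjusted p = 0.716). In PC3 its treated signal was above background on neither array, so that ratio, and the mean that includes it, are uncertain. KLK3, which encodes prostate-specific antigen, was not tested, since it was above background on both arrays only in MDA2b, where its log2 ratio was -0.03.

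Gene lists written before the data were examined were then compared with all other genes. The lists of genes reported as methylated in prostate cancer and of cancer-testis genes, which are normally active in germ cells, both lay higher with treatment. Of 34 tested prostate-methylated genes 27 had a mean above 0 and the median was 0.20 (camera with a preset correlation, adjusted p = 0.00126; adjusted p = 0.191 with an estimated correlation). One of them, the hyaluronan receptor CD44 at 0.86 ± 0.32, passed when adjusted over the list alone, and none when adjusted over all genes tested. The largest means of the list were those of the galectin LGALS3, at 1.58 ± 1.56, and of TFPI2, at 1.18 ± 2.13, which was carried by PC3. Of 16 cancer-testis genes 15 had a mean above 0, with a median of 0.32 (camera adjusted p = 2e-05; adjusted p = 0.191 with an estimated correlation). CTAG1B at 1.24 ± 0.84, MAGEB2 at 0.77 ± 0.46 and MAGEC1 at 0.64 ± 0.44 were the 3 that passed when adjusted over the list alone, and none passed over all genes tested. Without DU-145 the cancer-testis list no longer passed (camera adjusted p = 0.146). Its median was 0.23 in DU-145, 0.31 in LNCaP, 0.20 in MDA2b and 0.12 in PC3, so the rise was not confined to DU-145.

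Most known responders to deacetylase inhibitors moved in the direction of their lists. Of 25 genes known to be induced, 20 had a mean above 0 and the median was 0.34 (camera adjusted p = 0.000727; adjusted p = 0.191 with an estimated correlation). When adjusted over the list alone 4 genes passed, and only 3 of them were higher. These 3 were CDKN1A, the reductase gene DHRS2 at 1.77 ± 1.36 and HSPA2 at 0.73 ± 0.24. Of 14 genes known to be repressed, 12 had a mean below 0 and the median was -0.39 (camera adjusted p = 2e-05; adjusted p = 0.354 with an estimated correlation). TYMS, the replication genes MCM3 at -0.68 ± 0.50 and RRM2 at -0.67 ± 0.65, and UHRF1, a partner of DNMT1, at -0.66 ± 0.69 had the lowest means. None of these repressed genes passed over the list alone.

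Proliferation genes, genes of sterol and fatty acid synthesis, ribosomal protein genes and genes of the methylation and deacetylation machinery lay lower. Of 40 proliferation genes 34 had a mean below 0 and the median was -0.28 (camera adjusted p = 1.47e-08; adjusted p = 0.354 with an estimated correlation), with ZWINT at -0.83 ± 0.96 and TOP2A at -0.70 ± 0.89. Of 63 ribosomal protein genes 55 had a mean below 0 and the median was -0.19 (camera adjusted p = 1.47e-08; adjusted p = 0.398 with an estimated correlation). In DU-145 these medians had the other sign, at 0.17 for proliferation, 0.19 for ribosomal proteins and 0.15 for the repressed deacetylase inhibitor list. Of 21 genes of cholesterol synthesis and related lipid synthesis 15 had a mean below 0, with a median of -0.23 (camera adjusted p = 0.000176; adjusted p = 0.354 with an estimated correlation). The desaturase genes FADS2 at -0.91 ± 0.98 and SCD at -0.87 ± 0.90 had its lowest means. The 19 genes of the DNA methyltransferase and histone deacetylase list had a median of -0.09, 13 of them below 0 (camera adjusted p = 0.0263; adjusted p = 0.279 with an estimated correlation). Within none of these 4 lists did a gene pass when adjusted over the list alone.

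Genes of the unfolded protein and amino acid stress response lay higher, 14 of 19 with a mean above 0 and a median of 0.27 (camera adjusted p = 0.0263; adjusted p = 0.279 with an estimated correlation). CHAC1 stood at 0.75 ± 0.70 and the transcription factor gene ATF3 at 0.61 ± 1.12, which was carried by DU-145 and PC3, while PHGDH of serine synthesis stood at -0.76 ± 0.74, and none passed over the list alone. This list no longer passed without DU-145 (camera adjusted p = 0.494), without LNCaP replicate 1 (adjusted p = 0.187) or without MDA2b replicate 1 (adjusted p = 0.0768). With an estimated correlation none of the 19 lists passed, and 9 did with the preset one. Fry, which asks whether the genes of a list move one way on balance, passed for 4 lists, all higher: cancer-testis (adjusted p = 0.033), induced by deacetylase inhibitors (0.0404), antigen presentation (0.033) and fibroblast markers (0.0492).

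The remaining lists did not pass camera. Histone genes went both ways, with a median of 0.11 over 10 genes (adjusted p = 0.188). Of these genes, 6 passed when adjusted over the list alone. The 4 higher ones were led by H1-2 and H2BC4 at 1.16 ± 0.72, and H4C3 at -0.99 ± 1.02 was among the lower ones. Antigen presentation had a median of 0.11 over 15 genes (adjusted p = 0.124), and IFI30 and the class I light chain gene B2M, at 0.78 ± 0.21 and higher on all 8 arrays, passed over the list alone. Cell adhesion and junction genes had a median of 0.08 over 29 genes (adjusted p = 0.213), and the laminin chain gene LAMB3 at 1.60 ± 1.07 passed over the list alone together with CD44. Imprinted genes had a median of 0.01 over 15 genes (adjusted p = 0.213), with IGF2 past the threshold over the list alone. Genes of the p53 response had a median of 0.11 over 16 genes (adjusted p = 0.289), with CDKN1A past it over the list alone. Interferon-stimulated genes had 0.14 over 23 genes (adjusted p = 0.0895), androgen response genes 0.12 over 25 genes (adjusted p = 0.188) and neuronal and neuroendocrine genes 0.10 over 32 genes (adjusted p = 0.0807), with no gene past the threshold over any of these lists alone. Markers of other cells were at 0.14 over 8 genes for fibroblasts (adjusted p = 0.0857) and at 0.06 over 6 genes for leukocytes (adjusted p = 0.991). Endothelial markers and metallothioneins had 1 gene tested each, EMCN at -0.24 and MT3 at 0.15, and so no list test.

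**Figure D2:**
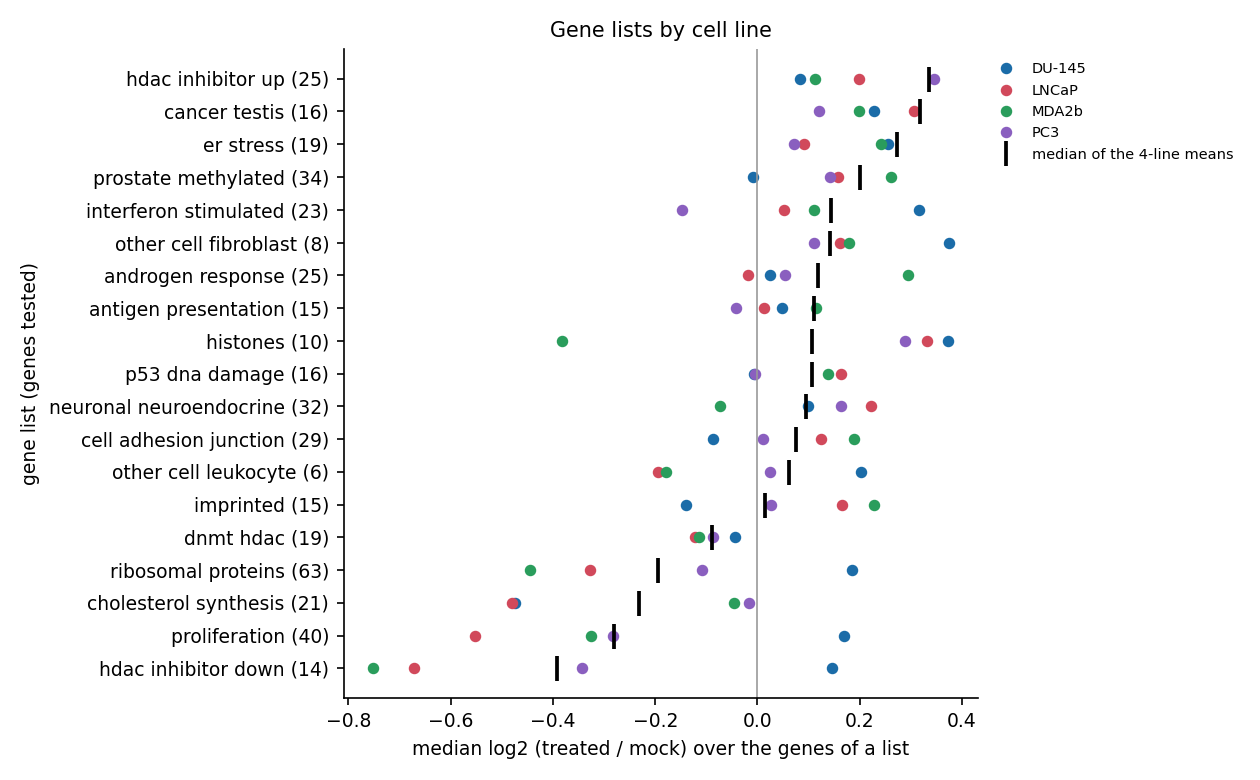
Median log2 ratio of treated over mock (horizontal axis) over the tested genes of each list (vertical axis, number of genes in brackets), as 1 coloured point per cell line, with a black bar for the median of the gene means over the 4 lines. The medians of DU-145 lie above 0 for proliferation, ribosomal proteins and genes repressed by deacetylase inhibitors, where those of the other lines lie below 0.

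Image analysis settings in the file headers split the arrays into 3 sets: the DU-145 pair with LNCaP replicate 2, LNCaP replicate 1 with the MDA2b pair, and the PC3 pair. TIMP1 had a mean log2 ratio of 2.20, 1.74 and 2.02 in the 3 sets in that order. Medians of the prostate-methylated list were 0.12, 0.25 and 0.14, and those of the cancer-testis list 0.37, 0.31 and 0.12. Proliferation stood at -0.12, -0.44 and -0.28 and the ribosomal protein list at 0.15, -0.54 and -0.11.

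Within each line, probes were counted that changed at least 2-fold in the same direction on both dye orientations, which is a count with no test. PC3 had 212 higher and 111 lower of 8989 probes above background, DU-145 81 and 51 of 8298, LNCaP 27 and 41 of 4866, and MDA2b 66 and 8 of 7975. Probes that changed at least 2-fold in opposite directions on the 2 arrays numbered 5 in PC3, 15 in DU-145, 25 in LNCaP and 45 in MDA2b. Across probes, which are not independent replicates, the log2 ratios of both orientations correlated at r = 0.54 in PC3, 0.26 in DU-145, 0.10 in MDA2b and 0.07 in LNCaP. In the brightest 10% of probes these were 0.81, 0.71, 0.62 and 0.35 in the same order. The changes in LNCaP and MDA2b were thus close to the dye and array noise for most probes.

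Ranks within a line are among probes with 1 gene symbol, and some probes without a symbol lay between or beyond the genes named. In DU-145 the largest increases of named genes were in germ cell genes. VCX stood at 6.87 on the log2 scale (6.63 and 7.12 on the 2 arrays). GAGE12F, not above background in mock cells on either array, was at least about 25.7-fold higher. Both belong to families of near-identical copies, so the member that was measured is uncertain. IFI27L2 followed at 4.64, the neurosecretory protein gene VGF at 4.16 and LRCH4 at 3.70. LPCAT1, of phospholipid remodelling, was the lowest gene with a symbol at -2.65, before the mucin MUC1 at -1.79 and the tetraspanin TSPAN1 at -1.68. In PC3 the chemokine genes CCL20 at 6.74 and CXCL8 at 4.56 led, followed by TFPI2, a serine protease inhibitor, at 4.38, the fatty acid binding protein gene FABP4 at 4.33 and the apoptosis inhibitor BIRC3 at 4.02. TMBIM4 at -3.18, the prostaglandin dehydrogenase HPGD at -2.74 and the semaphorin receptor NRP1 at -2.60 were the lowest with a symbol there. Mock signals of VCX, VGF and LRCH4 in DU-145 and of CCL20 in PC3 were above background on only 1 array. The same held for treated signals of TSPAN1 in DU-145 and of TMBIM4 and HPGD in PC3. The sizes of these ratios are therefore uncertain.

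LNCaP had its largest increases in IGFBP3, which binds insulin-like growth factors, at 3.10, the transcription regulator ID1 at 2.89, H1-2 at 2.69, clusterin, CLU, at 2.48 and IFI27L2 at 2.35. BNIP3 at -2.14, creatine kinase CKB at -1.89 and the glycolytic PGK1 at -1.81 were the lowest with a symbol. In MDA2b the galectin gene LGALS3 was not above background in mock cells and was at least about 7.50-fold higher. Progastricsin, PGC, stood at 3.30, UBTD1 and HPGD at 2.64 each and the calcium-binding S100A4 at 2.44. TMEFF2 at -1.89, TYMS at -1.86 and the histone H4C3 at -1.65 were lowest in MDA2b. Mock signals of IGFBP3 and IFI27L2 in LNCaP and of UBTD1 and HPGD in MDA2b were above background on only 1 array. The same held for treated signals of TMEFF2 and TYMS in MDA2b, so the sizes of these ratios are uncertain.

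**Figure D3:**
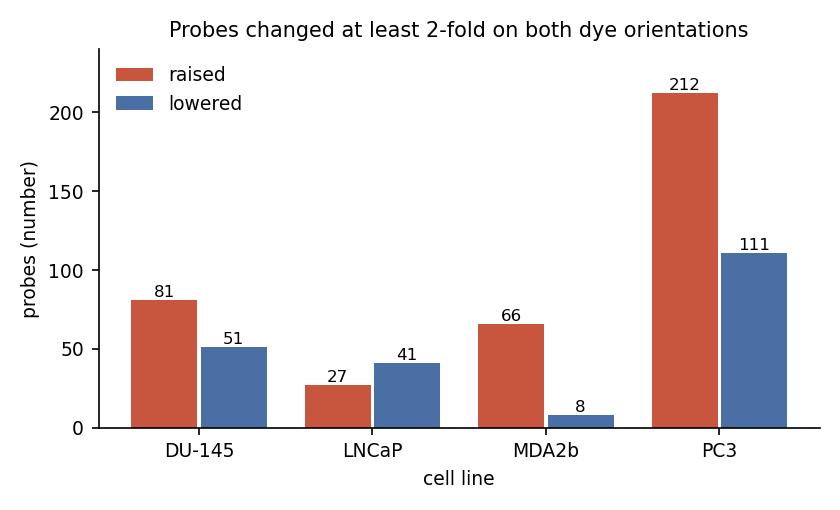
Number of probes (vertical axis) raised or lowered at least 2-fold on both dye orientations in each cell line (horizontal axis). PC3 has the most, with 212 raised and 111 lowered, and MDA2b the fewest lowered, with 8.

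The next comparison asked which genes responded differently between the lines, with the 8 arrays as separate values and dye orientation as a term, so that its p-values measure the spread between 2 hybridisations only. HPGD differed most among genes that went up at least 2-fold in one line and down in another: it stood at 2.64 in MDA2b and 1.05 in LNCaP, at 0.02 in DU-145 and at -2.74 in PC3 (limma F test, adjusted p = 9.84e-05). TSPAN1 was higher in LNCaP at 1.05 and lower in DU-145 at -1.68 (adjusted p = 0.00406). The mucin MUC5AC stood at 1.40 in MDA2b and -1.51 in PC3 (adjusted p = 0.00411), and the heparanase relative HPSE2 at 1.53 and -1.44 in the same lines (adjusted p = 0.00594). The trefoil peptide gene TFF1 stood at 1.93 in DU-145, 1.42 in MDA2b and -1.29 in PC3 (adjusted p = 0.0065), and the secreted glycoprotein gene STC2 at 1.22 in DU-145 and -1.18 in MDA2b (adjusted p = 0.0173). Of 9087 probes 189 passed, and 8 of them went up in one line and down in another by 2-fold on both arrays of each line. By the line means alone more of them did. The line farthest from the median of the 4 was PC3 in 106 of the 189, DU-145 in 42, MDA2b in 26 and LNCaP in 15.

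This count moved with the settings: it was 26 with a normexp offset of 10, 25 with the image analysis set as a term and 33 without the dye term. In the authors' value table it was 1. The image analysis term marked only the set of LNCaP replicate 1 with the MDA2b pair. With it HPGD (limma F test, adjusted p = 0.0411) and TFF1 (0.0331) still passed, while TSPAN1 (0.138), MUC5AC (0.0901), HPSE2 (0.244) and STC2 (0.365) did not. The PC3 pair is a set of its own, so no term can separate that line from its settings. The differences of HPGD and TFF1 that rest on PC3 are therefore not cleared by this. None of the 6 genes passed in the authors' value table, where HPGD came nearest (adjusted p = 0.0671).

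**Figure D4:**
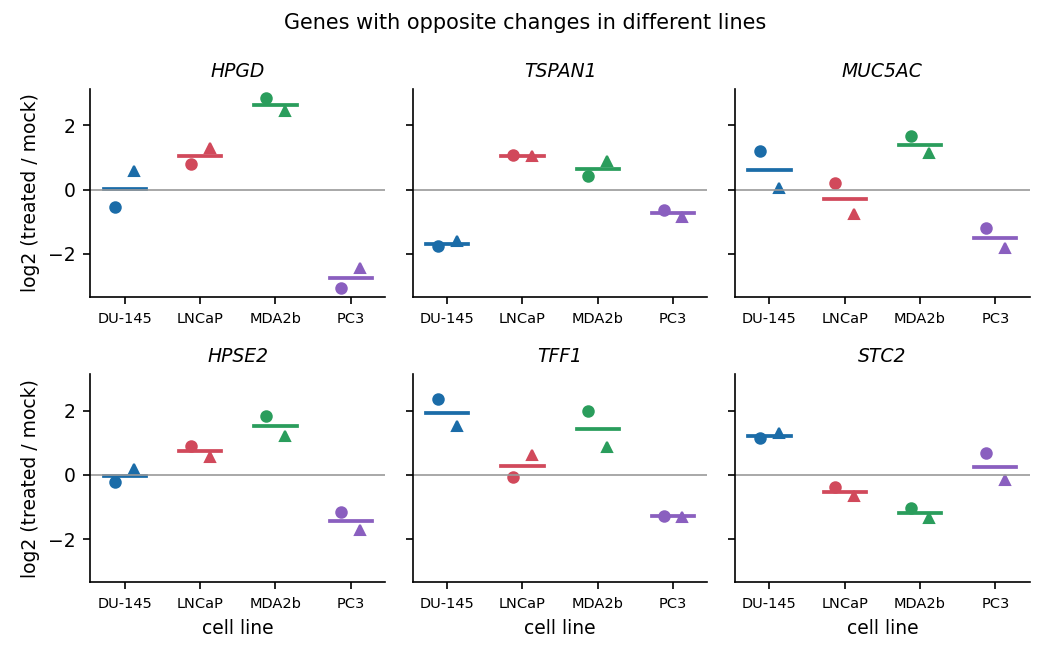
Log2 ratio of treated over mock (vertical axis) in each cell line (horizontal axis) for the 6 genes named in the comparison between lines. Circles are arrays with treated RNA in Cy5, triangles those with treated RNA in Cy3, and bars their mean; HPGD runs from -2.74 in PC3 to 2.64 in MDA2b.

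Genes raised in several lines were counted next. TIMP1 was raised at least 2-fold on both orientations in all 4 lines, and IFI27L2, H1-2 and CCK in 3. Another 22 genes were raised in 2 lines, among them CDKN1A and the cancer-testis gene CTAG1B in DU-145 and LNCaP, DHRS2, CXCL8 and the phosphatase DUSP1 in DU-145 and PC3, LAMB3 and ID1 in LNCaP and PC3, and PGC and the kallikrein KLK1 in LNCaP and MDA2b. The total of 26 genes compares with 3.29 for independent lists of the same sizes. Only FADS2, SCD, TYMS and ZWINT were lowered in 2 lines, against 0.737 for independent lists. DU-145 and PC3 shared 12 raised genes (1.30 if independent) and LNCaP and PC3 shared 9 (0.441 if independent). These numbers for independent lists give every gene above background in a line the same chance of a call. Chances can differ between probes with brightness and noise, so an excess does not by itself show a shared response. Across 2292 genes above background in all lines, the line averages correlated most between LNCaP and MDA2b (r = 0.34) and least between DU-145 and MDA2b (r = -0.09). Between single arrays of LNCaP and MDA2b, across 2863 probes, r ran from 0.02 to 0.33. It was highest for the replicate 1 arrays, which share dye orientation and image analysis set. The 2 arrays of LNCaP correlated at only 0.13 there and those of MDA2b at 0.15. Each line had its own mock RNA, so no control was shared. Without LNCaP the number raised in at least 2 lines was 15.

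Genes switched on were those not above background in mock cells and above it in treated cells on both arrays, and raised at least 2-fold on both. CCK met this in DU-145, where it was at least 2.36-fold higher, and in LNCaP, at least 2.57-fold. TIMP1, LAMB3 and the keratin KRT7 met it in LNCaP, with at least 2.49-fold, 2.26-fold and 3.37-fold. LGALS3 met it in MDA2b, at least 7.50-fold, and GAGE12F in DU-145, at least 25.7-fold. All these bounds are approximate, since the level set for the mock signal was not the limit of each spot. The count was 4 probes in DU-145, 8 in LNCaP, 9 in MDA2b and 7 in PC3, which are 27 different probes. Background set at 3 SD gave 49 calls in place of 28, 15 of them the same, and a 3-fold change gave 8.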

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

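The tests on the shared brightness of LNCaP and MDA2b arrays were chosen after the result had been seen; those of the gene lists were set before their percentiles were computed, with the shifts of the lists already known. Histone genes stood apart in MDA2b, where their median log2 ratio was -0.38 against 0.29 to 0.37 in the other lines; the gap makes up 0.889 of the range. Of 38 sets of 4 line values this was the only one so far apart, and chance alone sets off about 1 in 20.

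The following 6 genes responded differently between lines in the F test, whose spread is technical: HPGD (adjusted p = 9.84e-05), TSPAN1 (0.00406), MUC5AC (0.00411), HPSE2 (0.00594), TFF1 (0.0065) and STC2 (0.0173).

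Arabidopsis control spots, which should find no human RNA, were above background in the Cy3 channel for a median of 55.7% of spots (26.4% to 69.8% over the 8 arrays), against 5.66% in Cy5 and 0.261% of blank spots in Cy3. Human spots were above it for 64.0% in Cy3 and 33.2% in Cy5. Being above background in Cy3 alone is therefore weak evidence that a gene was expressed.

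LNCaP replicate 1 resembled MDA2b replicate 2 in spot brightness (r = 0.51 across bright probes, after removing each probe's mean) more than LNCaP replicate 2 (r = -0.18). Exchanged line labels would give the crosswise split, in which 530 probes were at least 4-fold apart on both arrays of each side. As labelled this held for 53 probes, against 4 for the split by replicate number. Outside the dim first column of the grid on LNCaP replicate 1 these were 400, 18 and 3. The 53 against 4 go with the labels and the 530 with an exchange, so the splits do not decide. Single genes, picked after their values were seen, go both ways. DSC2 follows the labels, with a mock signal over background of 3626 and 2197 on the LNCaP arrays against 444 and 194 on those of MDA2b. FOLH1 runs crosswise, with 633 and 3385 on the LNCaP arrays against 5170 and 725. A brightness difference between slides that crosses the lines may account for the crosswise split. The crosswise difference correlated with that of DU-145 minus PC3 at r = 0.582 across probes. DU-145 and PC3 differ in line as well as in slide, so this correlation does not separate the explanations. A low KLK3 signal in mock cells on LNCaP replicate 1, 46.9 against 30120 on replicate 2, is left open. It does not speak for an exchange, as KLK3 was at 28439 and 47018 on the MDA2b arrays. The KLK3 spot lies in that dim first column. The median signal of this column over both channels was 181 against 417 in column 4, a far smaller gap.

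Ribosomal protein and proliferation lists lay lower with treatment. Both medians lay at percentile 0 among 10000 lists of about equally bright genes. The central range of those lists' medians was -0.054 to 0.103 for proliferation and -0.059 to 0.102 for ribosomal proteins. For proliferation this argues against a normalization trend with spot brightness, as equally bright genes did not lie lower. The ribosomal list has a median brightness percentile of 98.6, where equally bright genes are hard to match. The trend is therefore left open for it. Genes of these lists move together (estimated correlations 0.45 and 0.52), so percentile 0 does not measure significance. No test decides between the image analysis sets and the lines, which overlap, and a slower growth of treated cells is a biological explanation that was not tested.

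Prostate-methylated and cancer-testis lists lay higher with treatment. The same trend is argued against here, with both medians at percentile 100 of 10000 lists of equally bright genes. The cancer-testis list had a camera adjusted p of 0.146 without DU-145. Its median in DU-145, 0.23, lay below the 0.31 of LNCaP, so the lost call does not show that the rise comes from DU-145. Release from methylation would be the biological explanation the design gives, and it stays a hypothesis, since methylation was not measured here.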

How the results depend on the processing

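Alternatives added after the data were seen are MDA2b replicate 1 as deposited, print-block loess, the limit of 4 SD, the image analysis terms, the overlap without LNCaP and the lists without single arrays. The choice between keeping and leaving out spots called empty was reversed after the data were seen. Across lines 1 probe, TIMP1, passed. It was 0 with no background correction, with empty spots left out (317 of 4951 probes at an unadjusted p under 0.05), in the authors' value table, with MDA2b replicate 1 as deposited and with the limit of 4 SD (limma in each case), and 0 with any line left out; leaving out single arrays gave 0 (without MDA2b replicate 2) to 2 (without MDA2b replicate 1). It was 3 with probes above background in all lines, 8 with the line and 7 with the image analysis set as a random block, which both take 8 arrays of 4 lines as nearly separate values, and 249 with a term per line, which uses the technical spread. TIMP1 itself stayed between 1.77 and 2.21 on the log2 scale, with adjusted p from 7.77e-06 to 0.731. Within lines, 597 probes (64.7% of them higher) became 391 (74.9% higher) with no background correction, 2005 at 1.5-fold and 157 at 3-fold. Between lines, 189 became 26 with an offset of 10, 386 with spot medians, 1 in the value table, 82 with MDA2b replicate 1 as deposited, 33 with no dye term, 25 with the image analysis term and 42 at an adjusted p under 0.01. Of the 9 lists 0 passed with an estimated correlation. Fry passed 4 lists, but antigen presentation and fibroblast markers among them were not of the 9. Lists past camera numbered 7 to 11 with a line left out and 8 or 9 without single arrays. Overlap fell from 26 to 15 without LNCaP. Genes switched on went from 28 to 49 at 3 SD, 8 at 3-fold and 15 with no background correction. Apart from fewer probes tested, stricter thresholds or fewer samples, the cause was not tested. Aquantile leaves ratios as they are, so it tests nothing for them. No named gene across lines and no list that had passed reversed its direction. Lists that had not passed changed direction in 5 values. Among other results, 407 values of single genes across lines kept their side of the threshold, 23 gained it and 10, all of TIMP1, lost it.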

Other observations

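The genes in the first 2 paragraphs were picked after their values had been seen, and the test on signs of lines was set before. No gene lower on all 8 arrays reached 2-fold, but several lay lower in every line without passing. LONP1, a mitochondrial protease, had a mean log2 ratio of -0.87 ± 0.09 (SD, n = 4 lines, limma adjusted p = 0.258), the RNA-binding TAF15 -0.75 ± 0.16 (adjusted p = 0.327), the pentose phosphate enzyme transketolase, TKT, -0.74 ± 0.36 (adjusted p = 0.5) and the glycolytic enolase ENO1 -0.67 ± 0.32 (adjusted p = 0.517).

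Single genes of the prostate epithelium are given here without a test of LNCaP against MDA2b. TMPRSS2, an androgen-induced protease, stood at -1.56 and -1.92 on the LNCaP arrays and at 0.68 and 0.94 on the MDA2b arrays (limma F test over all 4 lines, adjusted p = 0.0129, technical spread only). MSMB, a secreted seminal protein, stood at 2.15 and 1.18 on the MDA2b arrays, with a line mean of 1.66 against -0.18 in LNCaP (same test, adjusted p = 0.0465). Other genes agreed, as PGC and KLK1 were raised at least 2-fold on both arrays in both of these lines.

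With the signs of whole line averages changed, 8 different patterns are possible, and 1 of them, the real one, gave as many probes as were called across lines (1, against at most 0 in any other). These are too few patterns for a share under 0.05.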
